A study of Mus musculus with 2 samples.

How the data were processed

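MicroRNA sequencing was carried out on hindbrain of B6NCrl mouse embryos at embryonic day 16.5, with both sexes pooled. The series holds 1 group of 2 biological replicates, each a separate pool of embryos with its own library. Replicate 2 was pooled from 37 embryos per the labels, and the number for replicate 1 was not given in the sources used here. Per the labels, total RNA was used and the libraries cover RNA shorter than the limit of 30 nt stated for the size range.

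The deposited values are raw read counts per gene, which the authors obtained on mm10 with the GENCODE M4 annotation, per the text that came with each sample. The aligner, the counting program and their versions are not given in the sources used here. Each table has 3 count columns, for reads on either strand and on each strand alone, after 4 summary lines for unmapped reads, reads that map to several places, reads outside any listed gene and ambiguous reads. The first column was the sum of the other 2 for every gene. The summary lines name no gene and stayed out of the library totals. Per the deposited summary lines, unmapped reads made up 15.5% and 15.2% of all reads in replicates 1 and 2, multimapping reads 34.5% and 35.1%, and reads outside listed genes 3.75% and 3.93%. No read was ambiguous. Reads that fit several loci are reported only as that total, so a hairpin that shares its mature sequence with another locus can hold fewer counts than the microRNA it makes.

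The strand column with the larger total was used as the sense count, by a rule set before the data were examined, as were the lists, the pairs, the tests and the other settings tried, apart from those named as later additions. Gene identifiers were matched without their version to GENCODE M21, which uses the same assembly (GRCm38, mm10). Of the 1973 genes listed, 1894 matched, all annotated as microRNA genes. The other 79 held 8 sense counts in both libraries together. Coordinates, strands and host genes are those of GENCODE M21. A further 308 microRNA genes of that release had no entry of their own and were not analysed here on the sense strand.

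CPM is the count of a gene per 1000000 sense counts of its library. Levels are the mean ± SD of 2 libraries. Intervals are 95% exact binomial intervals, and the limit for a count of 0 is 3 counts, which is 0.589 CPM in replicate 1 and 0.673 CPM in replicate 2. Both cover counting error only, because reads without molecular identifiers are not independent molecules. A gene was called detected with at least 10 counts in both libraries. The spread between replicates was estimated as edgeR's common dispersion without a contrast.

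With 1 group there was no comparison between conditions. A ratio of 2 microRNAs was called different only when it had the same sign in both libraries and its mean log2 value exceeded 2 SD, since an exact sign-flip test over 2 libraries cannot go below p = 0.5. This rule covers the spread between the 2 libraries only, so a bias of counts that both share would not show. The 2 libraries were compared gene by gene with an exact two-sided binomial test against TMM-scaled totals, over 401 genes with a summed count of at least 20, with Benjamini-Hochberg adjustment at 0.05. This test measures counting noise and compares the libraries, not conditions. On simulated data with counting noise only, it called 66% of genes changed 1.25-fold, 80% of those changed 2-fold and 96% of those changed 4-fold, and 3 of 204 unchanged genes, in a step of 399 genes. Medians of gene lists were set against 10000 random lists, of all genes for levels and of genes with similar levels for library ratios. Levels of identical-copy and single-copy hairpins were compared by a two-sided permutation test over genes with 100000 resamples, on log2(CPM + 1).

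The text names the 20 genes of highest mean CPM and the pairs. It draws on all counted members of the HOX-cluster, choroid plexus and multiciliated, oligodendrocyte-lineage, erythroid, vascular, liver and sensory organ lists, and on the 4 most abundant members of every other list. It also names the 10 genes with the largest log2 ratio between the libraries among those past the threshold with a mean of at least 100 CPM. Other genes named were chosen after their values were seen. Alternatives were the unstranded counts, TMM and DESeq2 scaling, a total without the most abundant gene, other count minimums and pseudocounts, the omission of identical copies, each replicate alone, and edgeR's exact test at an assumed biological coefficient of variation (BCV) of 0.1 and, added after the data were seen, at the BCV estimated from the libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.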

Results

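MicroRNAs of the mouse hindbrain, the part of the brain that forms the medulla, pons and cerebellum, were profiled at embryonic day 16.5. The data comprise 2 libraries from 2 pools of embryos. Replicate 1 held 11018624 reads, of which 5097205 were sense counts on microRNA genes, and replicate 2 held 9729498 reads with 4460836 sense counts. A sense count was found for 680 genes in replicate 1 and 667 in replicate 2, and 385 genes had at least 10 counts in both.

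The hindbrain profile was led by Mir99a, a microRNA of the miR-99/100 family, with 17.7% ± 1.46 of all sense counts (SD, n = 2). Mir99a (ENSMUSG00000065530.1) lies on chromosome 16 from 77598936 to 77599000 (mm10), in an intron of the long noncoding gene Mir99ahg. It was followed by Mirlet7g at 71186 ± 3958 CPM (SD, n = 2; chromosome 9, 106178840 to 106178927, an intron of Wdr82) and Mir10a at 60429 ± 3641 CPM. Mirlet7i reached 44786 ± 741 CPM, Mir487b of the imprinted Dlk1-Dio3 region 42616 ± 8979 CPM, and Mir100 39011 ± 2541 CPM. Mir335, in an intron of the imprinted gene Mest on chromosome 6 (30741299 to 30741396), reached 34205 ± 4030 CPM. Mir10b, the endothelial Mir126a and Mir130a completed the first 10 genes, which together held 55.3% ± 1.45 of the counts (SD, n = 2). The exact binomial 95% interval was 54.2% to 54.3% in replicate 1 and 56.3% to 56.4% in replicate 2, so the libraries differed by more than counting error. The next 10 were Mir99b, Mir149, Mir30e, Mir26b, Mir181c, Mir17, Mir127, Mir369, Mir382 and Mir30a, from 19252 ± 641 CPM for Mir99b to 8745 ± 807 CPM for Mir30a. The first 20 genes held 68.8% and the first 100 held 95.7% of the counts. This ranking leaves out multimapping reads, 34.5% and 35.1% of all reads in replicates 1 and 2, and microRNA genes without an entry. A microRNA whose hairpins share sequence can therefore rank below its amount.

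**Figure D1:**
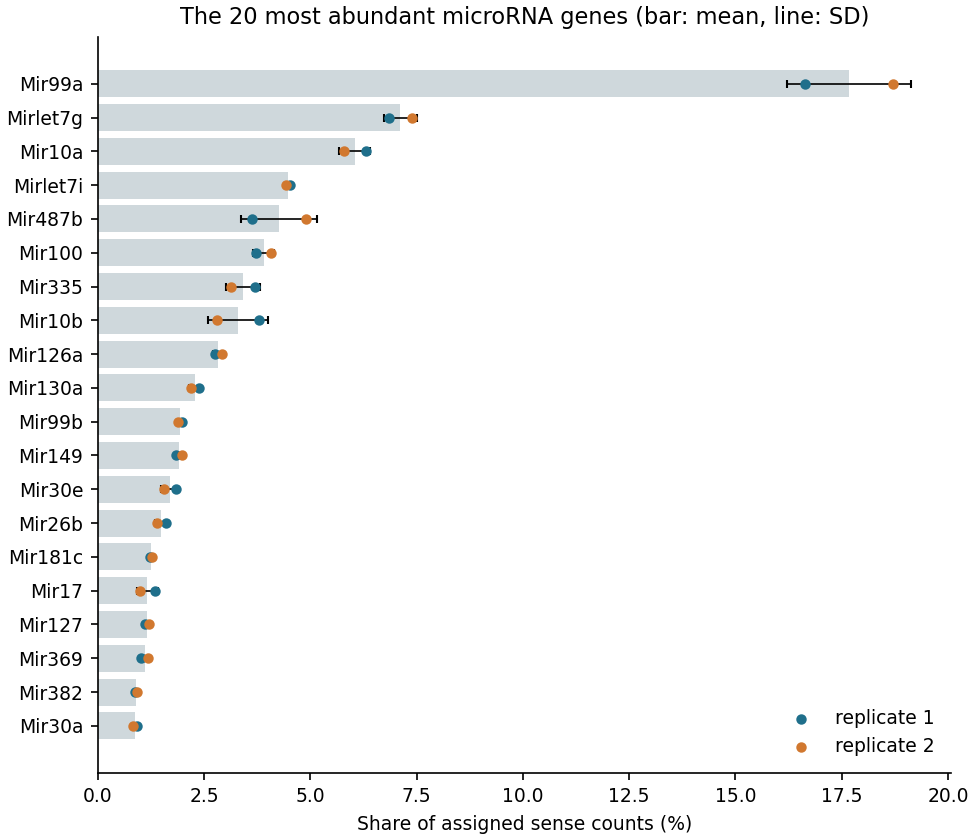
Share of assigned sense counts (%, x axis) of the 20 most abundant microRNA genes, with bars at the mean of 2 libraries, lines at 1 SD and points for each library. Mir99a holds 17.7% on average and the first 10 genes together 55.3%. Multimapping reads are left out of the shares.

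MicroRNAs that lie inside the Hox clusters, whose genes pattern the hindbrain along its axis, held 9.46% ± 1.10 of the counts (SD, n = 2). Nearly all of this came from Mir10a, next to Hoxb4 on chromosome 11 (96317165 to 96317274), and Mir10b, in introns of Hoxd3 and Hoxd4 on chromosome 2 (74726070 to 74726137) at 33002 ± 7054 CPM. Mir10b was lower than Mir10a in both libraries, with a mean log2 ratio of -0.89 ± 0.22 (SD, n = 2), past the limit of 2 SD. Mir615, in an intron of Hoxc5, reached 1105 ± 204 CPM. Members at more posterior Hox positions were far lower, with Mir196b at Hoxa9 at 101 ± 96.0 CPM and Mir196a-2 between Hoxc9 and Hoxc10 at 5.81 ± 1.29 CPM. Mir196a-1 near Hoxb9 had 0 counts, which allows up to 0.589 CPM in replicate 1 and 0.673 CPM in replicate 2. Mir196a-1 and Mir196a-2 make the same mature sequence, so their levels are uncertain.

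The neuron-enriched list held 27.0% ± 1.61 of the counts (SD, n = 2), with 34 of 37 counted members detected. Mir99a alone supplied most of it, and without Mir99a in the list and the total the share was 11.4%. Mir100 and Mir149, the latter in an intron of Gpc1 at 19035 ± 935 CPM, came next, followed by Mir137 at 8178 ± 1384 CPM. Of the 37 counted members, 19 are also on the identical-copy list, and without those 19 the share was 25.8%. Mir9 and Mir124, which are among the best known neuronal microRNAs, had few counts at most of their counted hairpins. Mir9-3 had 2474 and 2082 counts, while Mir9-2 had 4 and 5, and the Mir124a-1, Mir124a-2 and Mir124a-3 hairpins had 22, 11 and 1 counts in replicate 1. Each of these hairpins shares its mature sequence with other loci, so these counts do not measure the amount of miR-9 or miR-124. These Mir9 and Mir124a hairpins were singled out after their values were seen.

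The let-7 family, which rises as tissues differentiate, held 14.2% ± 0.407 of the counts (SD, n = 2), and all 10 counted members were detected. Mirlet7g and Mirlet7i led, followed by Mirlet7d at 8716 ± 125 CPM and Mirlet7b at 8425 ± 751 CPM. Of 14 listed members 10 were counted, and 5 of these are on the identical-copy list. Mirlet7e and Mirlet7f-1 had no entry of their own, and the opposite strand at their positions held 5640 and 95.5 CPM. The share and the order within the family are therefore uncertain. The miR-17-92 cluster and its paralogues, which are associated with proliferation, held 3.31% ± 0.584, led by Mir17 at 11640 ± 2498 CPM, Mir93 at 6180 ± 1055 CPM, Mir106b at 5954 ± 736 CPM and Mir20a at 4564 ± 752 CPM. The miR-17-92 cluster exceeded the miR-106b-25 cluster by a log2 ratio of 0.70 ± 0.07 and the miR-106a-363 cluster by 5.28 ± 0.04 (SD, n = 2), both past the limit of 2 SD. Mir19b-1, Mir19b-2, Mir92-1 and Mir92-2 of these clusters are on the identical-copy list, so both ratios rest in part on uncertain counts. The clusters of pluripotent cells held 0.0779% ± 0.0119, led by Mir302a at 296.7 ± 36.0 CPM, Mir302d and Mir302b, with Mir302c at 26.5 ± 8.01 CPM.

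The imprinted Dlk1-Dio3 region, most of whose microRNAs are made on the maternal chromosome, held 11.7% ± 1.22 of the counts (SD, n = 2). Unlike the other detected members, Mir3071 lies on the minus strand in GENCODE M21, in an exon of the protein-coding gene Rtl1. Its reads were counted with GENCODE M4, and the strand of this entry in that release was not checked. Parental origin was not measured. Of 60 listed members 51 were counted. Of the 51 counted members, 1 (Mir496b, with 0 counts) lies on chromosome 19, and 44 were detected, all between 109563692 and 109747960 on chromosome 12. Mir487b, Mir127, Mir369 and Mir382 supplied 63.7% of the list. Among the genes that these shares leave out are Mir376a, Mir409, Mir380 and Mir299a, which lie in the same interval but had no entry of their own. The opposite strand at their positions held 5858, 4706, 824 and 540 CPM. Levels ranged from 17.4 CPM for Mir1188 to 42616 CPM for Mir487b, a range of 11.1 in replicate 1 and 11.4 in replicate 2 on the log2 scale. The rodent Sfmbt2 intronic cluster, known from placenta, held 0.526% ± 0.0172, with 10 of 69 members detected and Mir467e, Mir467d, Mir467c and Mir669o the most abundant. Members of the Sfmbt2 cluster are close copies of each other and their single levels are uncertain.

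**Figure D2:**
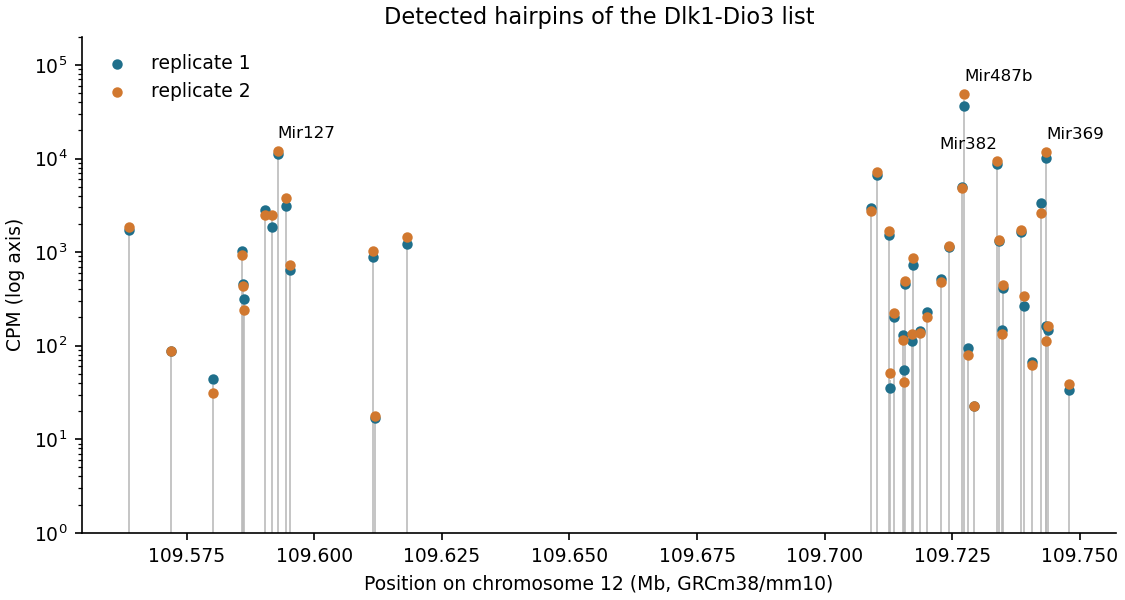
Level of the 44 detected hairpins of the Dlk1-Dio3 list in each library (CPM, log axis) against position on chromosome 12 (Mb, mm10), with grey lines up to the mean. Mir487b is the highest at 42616 CPM on average.

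Lists for particular cell types differed widely in level. The choroid plexus and multiciliated list held 0.972% ± 0.0582 of the counts (SD, n = 2), and all 7 members were detected. It was led by Mir449a, in an intron of Cdc20b, at 3869 ± 303 CPM, Mir204, in an intron of Trpm3, at 3588 ± 682 CPM and Mir34c at 2177 ± 205 CPM. Mir34b reached 75.0 ± 1.81 CPM, and Mir211, Mir449b and Mir449c stayed under 10 CPM. The oligodendrocyte-lineage list held 0.393% ± 0.0451, with Mir219a-2 at 1648 ± 261 CPM, Mir138-1 at 1029 ± 136 CPM, Mir138-2 at 686 ± 38.1 CPM, Mir338 at 417 ± 16.5 CPM and Mir219a-1 at 153 ± 31.9 CPM. Of its 5 members, 4 are also on the identical-copy list, and without them the share was 0.0417%. The miR-183 cluster of sensory cells held 0.371% ± 0.0409, with Mir183 at 1768 ± 78.1 CPM, Mir182 at 1439 ± 284 CPM and Mir96 at 499 ± 46.5 CPM. Mir183 over Mir182 gave a log2 ratio of 0.31 ± 0.22 (SD, n = 2; 0.15 and 0.47 in replicates 1 and 2), within the limit of 2 SD.

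The vascular list held more counts than the lists for blood cells and other organs. The vascular list held 3.56% ± 0.123 of the counts (SD, n = 2), with Mir126a, in Egfl7, at 28326 ± 1204 CPM, Mir143 at 7155 ± 19.6 CPM and Mir145a at 114 ± 8.82 CPM. Mir143 exceeded Mir145a by a log2 ratio of 5.97 ± 0.11 (SD, n = 2), past the limit of 2 SD. Mir145b had 0 counts, under the same limits as Mir196a-1. The erythroid list held 0.0211% ± 0.000661, with Mir451a at 105 ± 10.7 CPM, Mir144 at 72.7 ± 16.2 CPM and Mir486 at 33.0 ± 1.03 CPM, and Mir451a over Mir144 gave 0.55 ± 0.47 (log2, SD, n = 2; 0.22 and 0.88 in replicates 1 and 2), within the limit of 2 SD. The leukocyte list held 0.0455% ± 0.00288, led by Mir223 at 170 ± 25.9 CPM, Mir155, Mir150 and Mir146. With unstranded counts it held 0.0711%, since the opposite strand of Mir142b, where Mir142 lies, held 273 ± 39.1 CPM, more than Mir223. Mir122 of hepatocytes reached 41.5 ± 0.649 CPM. The endocrine and pancreatic list held 0.126% ± 0.00349, led by Mir375 at 598 ± 7.38 CPM, Mir217, Mir216b and Mir216a. The mesenchymal and fibroblast list held 0.390% ± 0.0376, led by Mir21a at 3186 ± 241 CPM, with Mir214, Mir29a and Mir29c next. The epithelial list held 0.0148% ± 0.00535, led by Mir429 and Mir200c, followed by Mir200b and Mir141. The muscle list held 0.0402% in replicate 1 and 0.00446% in replicate 2.

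**Figure D3:**
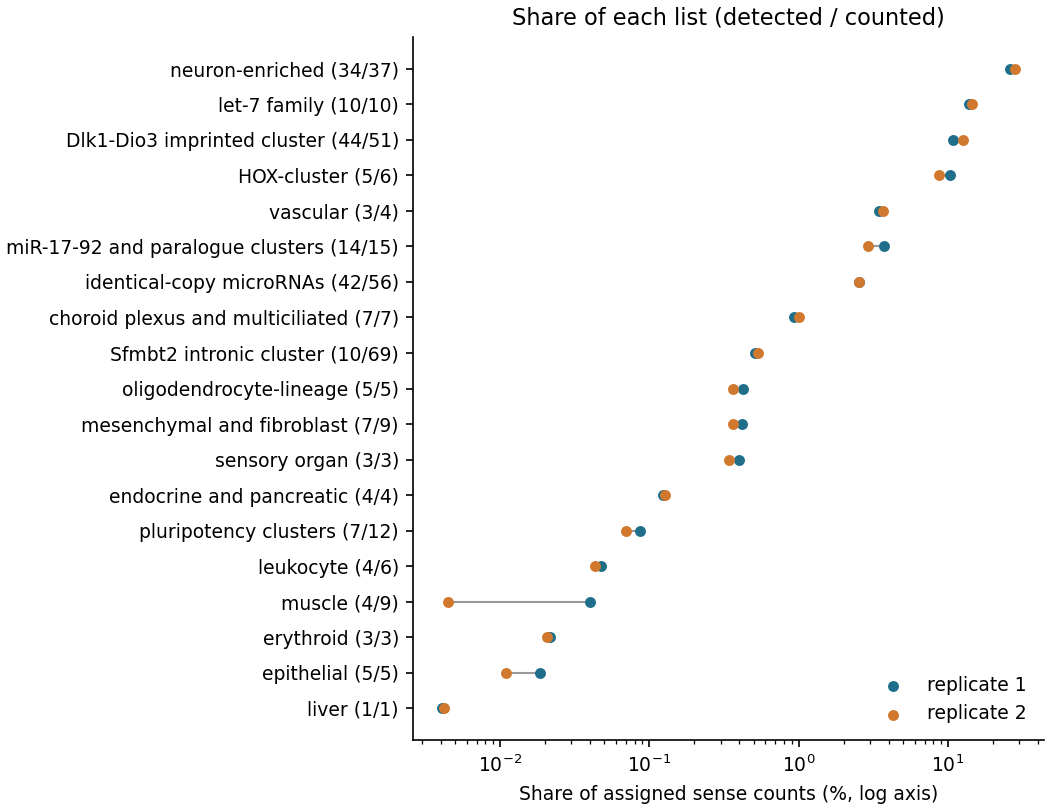
Share of assigned sense counts (%, log axis) of each microRNA list, with 1 point per library joined by a line and the number of detected and counted members beside each name. The muscle list lies at 0.0402% in replicate 1 and 0.00446% in replicate 2, the widest gap of all lists.

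The libraries differed most in Mir206, a skeletal muscle microRNA, with 1884 counts in replicate 1 and 108 in replicate 2. Mir206 was 14.6-fold higher in replicate 1 after TMM scaling (log2 ratio of replicate 2 over 1 of -3.87, exact binomial 95% interval -4.16 to -3.59). Mir196b was 4.92-fold higher in replicate 1 on the same scale, with 859 and 146 counts (log2 ratio -2.30, interval -2.56 to -2.04). Mir206 and Mir133b lie on chromosome 1 in exons of the noncoding gene Gm28653, and Mir133b had 26 and 3 counts. The cardiac and slow-muscle Mir499, in an intron of Myh7b, had 61 and 25 counts, while Mir208b, in an intron of Myh7, had 58 and 44 and did not pass (log2 ratio -0.14, interval -0.74 to 0.45). Of the other largest differences, Mir214 (-0.93), Mir483 of the Igf2 gene (-0.53) and Mir106a (-0.50) were higher in replicate 1 on the log2 scale. Mir129-2 (0.90), Mir195a (0.59), Mir129-1 (0.57), Mir433 (0.51) and Mir487b (0.50) were higher in replicate 2.

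Under the exact binomial test, 186 of 401 genes passed, 98 higher in replicate 1 and 88 in replicate 2, and 8 differed by at least 2-fold. With plain library totals in place of TMM scaling, which shifts log2 ratios by -0.06, 193 passed, 131 higher in replicate 1 and 62 in replicate 2. edgeR's exact test of 1 library against the other, at an assumed BCV of 0.1, called 7 genes, which were Mir206, Mir196b, Mir5126, Mir214, Mir129-2, Mir133b and Mir429. At the BCV of 16.02% estimated from these libraries it called 3, which were Mir206, Mir196b and Mir5126. That estimate comes from the same differences that were tested, and it was 11.6% without Mir206 and Mir196b. Of the 8 genes at 2-fold or more, Mir5126 alone was higher in replicate 2, with 22 and 64 counts. Without the minimum summed count of 20, 12 genes passed at 2-fold or more, 6 in each direction.

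By the exact binomial test, which allows for counting noise only, several lists held members that differed between the libraries. edgeR's exact test at the assumed BCV of 0.1 called 0 members of the miR-17-92, Dlk1-Dio3 and vascular lists, 2 of the muscle list (Mir206 and Mir133b), 1 of the HOX-cluster list (Mir196b), 1 of the epithelial list (Mir429) and 1 of the mesenchymal list (Mir214), all higher in replicate 1, and Mir129-2 of the neuron-enriched and identical-copy lists, higher in replicate 2. Of 14 tested members of the miR-17-92 and paralogue clusters, 9 were higher in replicate 1 and 0 in replicate 2 (10 and 0 when adjusted over the list alone), Mir17 by a log2 ratio of -0.38. The median of -0.24 lay at percentile 0.440 of random lists of similar level. Of 44 members of the Dlk1-Dio3 list, 24 were higher in replicate 2 and 6 in replicate 1 (24 and 6 when adjusted over the list alone), against 19 and 12 with plain totals, and the median of 0.13 lay at percentile 99.8. Among the 5 tested HOX-cluster members, 4 were higher in replicate 1 and 0 in replicate 2, with or without adjustment over the list alone. The muscle list had 3 of 5 tested members higher in replicate 1 and the epithelial list 2 of 5 (Mir429 and Mir200c), with 0 higher in replicate 2 in both and the same numbers adjusted over the list alone. The vascular list had 3 of 3 higher in replicate 2, but 1 with plain totals. Hairpins of one cluster are not independent, and these percentiles describe the 2 libraries only.

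The libraries were otherwise close. Across the 385 genes detected in both, Pearson's r of log2(CPM + 1) was 0.995 and Spearman's rho 0.993, where genes are not independent replicates. The median absolute log2 difference was 0.17, and 93.5% of genes lay within 1.5-fold. edgeR's common dispersion gave a BCV of 16.02%, and 11.6% without Mir206 and Mir196b.

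**Figure D4:**
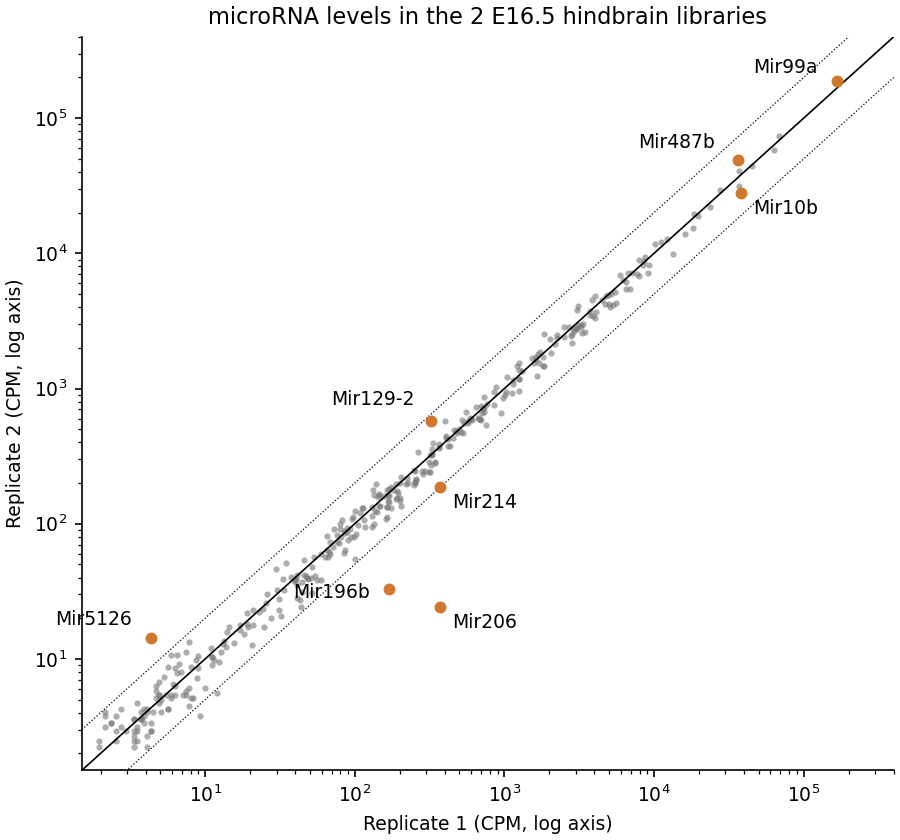
Level of the 385 detected microRNA genes in replicate 1 (x axis) and replicate 2 (y axis), both in CPM on log axes, with the line of equality and dotted lines at 2-fold. Mir206 (370 and 24.2 CPM) and Mir196b (169 and 32.7 CPM) lie outside the 2-fold lines, higher in replicate 1.

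Hairpins on the identical-copy list, such as Mir181a-1, Mirlet7f-2, Mir128-1 and Mir125b-2, together held 2.54% ± 0.00255 of the counts (SD, n = 2). The median level of the 42 detected was 202 CPM, against 280 CPM for the 139 detected members of the other lists, a log2 difference of -0.48 (two-sided permutation test, p = 0.533). It was -0.73 without replicate 2 (permutation p = 0.288) and -0.37 without replicate 1 (permutation p = 0.576). No difference between the classes was shown, and against all other detected genes the sign turned, to 0.52 (permutation p = 0.427). Multimapping reads came to 74.6 and 76.5 per 100 assigned sense counts in replicates 1 and 2, so the counts leave out a large part of the reads. With these reads in the total every share is smaller, 31.5% in place of 55.3% for the first 10 genes. None of these reads were added to a gene, and how many of them come from microRNAs is not known.

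Most reads on listed genes lay on the sense strand, 97.6% in each library. The opposite strand held 125700 counts in replicate 1 and 111380 in replicate 2.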

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

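The test on the opposite strand and the tests on Mir206 and Mir196b were chosen only after the results were seen. Reads on the opposite strand of listed genes, a column outside the main measurement, made up 2.41% of assigned reads in replicate 1 and 2.44% in replicate 2, above the limit that a count of 0 allows. They gathered on 11 entries that held more opposite-strand than sense reads in both libraries. The largest were Gm25252 on chromosome 12 with 28663 and 27183 opposite-strand counts and Gm25927 on chromosome 17 with 29047 and 24901. A candidate explanation is a microRNA gene on the other strand that the counting annotation did not hold. All 11 entries, or 100%, overlap such a gene in the later GENCODE release, among them Mir376a at Gm25252, Mirlet7e at Gm25927, Mir409 at Gm24321, Mir191 at Gm24083 and Mir378a at Gm25301. The 11 entries hold 99.8% of opposite-strand reads in each library, and 32 of all listed genes have such a partner. No biological explanation was tested.

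Mir206 and Mir196b were lower in replicate 2 by log2 ratios of -3.87 and -2.30. Counting noise is argued against by the counts of 1884 and 108 for Mir206 and 859 and 146 for Mir196b: their exact binomial intervals, made simultaneous over all tested genes, stay below -1.82, while the 40 tested genes nearest in level to each gene lay within 0.93 and 0.81 of 0, a spread that includes noise from reads that are not independent. A general rise of all non-neural tissue in the replicate 1 pool cannot be decided. The lists moved apart (permutation p = 0.0048 over 33 members of 8 lists without Mir206, 0.0253 without the muscle list, and 0.0012 and 0.0088 with hairpins of one cluster averaged). These permutations are over members, not pools. A list with a high level in both pools, such as the vascular list with Mir126a at 28326 CPM, can hide a small addition. The 12 vascular, erythroid, leukocyte and liver members had a median log2 ratio of 0.0356 (bootstrap interval -0.15 to 0.19). Endocrine and pancreatic members had one of 0.11 with 0 of 4 below 0, epithelial members -0.39 with 5 of 5 below 0 and mesenchymal members -0.22 with 6 of 8. The lists thus did not fall by a like amount, and a rise of single tissues stays open. Muscle tissue in the replicate 1 pool cannot be told apart from an equal share. The other muscle members together had a log2 ratio of -0.61 (166 and 91 counts, exact binomial interval -0.995 to -0.23). That ratio rests on Mir133b, which lies in the same noncoding gene as Mir206, and on Mir499. It was -0.41 (-0.81 to -0.02) without Mir133b and -0.07 (79 and 63 counts, -0.57 to 0.43) without both. Most of the counts left without both came from Mir208b (58 and 44). The muscle hairpins Mir1a-1, Mir133a-1 and Mir133a-2, on the identical-copy list, had 0 counts in both libraries and could not show a change. The value without both therefore cannot decide the question. More caudal tissue in the replicate 1 pool cannot be told apart from an equal share either, since Mir10b (-0.37), Mir615 (-0.31) and Mir10a (-0.06) were higher in replicate 1 by a test that covers counting error only, while Mir196a-2, at a Hox position like that of Mir196b, had 25 and 30 counts and a log2 ratio of 0.52 (interval -0.29 to 1.35); these tissues were weighed as differences in what was pooled, and with 1 group no biological explanation was tested.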

How the results depend on the processing

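The alternatives that counted multimapping reads in the total, compared all listed members, defined copies by 20 shared bases, left out the muscle, epithelial, mesenchymal and HOX-cluster lists, or used edgeR's exact test at the estimated BCV were chosen after seeing the data. No paired analysis was possible because the series has 1 group. Results that need both libraries, the agreement and the differences between libraries, could not be computed without either replicate. The 6 pairs kept their call with unstranded counts and their sign in each library, while other scalings act equally on both sides of a ratio. TMM and DESeq2 scaling moved no list share by more than 1 SD. For 2 libraries such factors offset each other (1.02 and 0.978 for TMM), so the mean of both hardly moves by construction. Detected genes numbered 610 with at least 1 count and 208 with at least 100 CPM in both libraries. Of the differing genes, edgeR's exact test at a BCV of 0.1 called 7 in place of 186, of which 4 by at least 2-fold, in place of 8. At the BCV estimated from the libraries it called 3, all 3 by at least 2-fold. The number at 2-fold was 12 without a filter, 6 in each direction, 2 with a summed count of at least 100 and 4 without the 4 lists named above, where fewer genes were tested. Spearman's rho was 0.942 over all genes with any count. The log2 difference between identical-copy and single-copy hairpins turned to 0.52 against all other detected genes, 0.23 with all listed members and 0.28 with copies defined by sequence, with permutation p from 0.427 to 0.841, and the cause was not tested. Without Mir99a in the total or in its list, the first 10 genes held 48.1%, and list shares in percent were 11.4 (neuron-enriched), 11.5 (HOX-cluster), 0.477 (oligodendrocyte-lineage), 1.18 (choroid plexus and multiciliated), 17.3 (let-7 family), 4.02 (miR-17-92), 0.0945 (pluripotency), 14.2 (Dlk1-Dio3 imprinted cluster), 0.639 (Sfmbt2 intronic cluster), 0.0256 (erythroid), 0.0553 (leukocyte), 4.33 (vascular), 0.00504 (liver), 0.45 (sensory organ), 0.153 (endocrine and pancreatic), 0.474 (mesenchymal and fibroblast), 3.09 (identical-copy microRNAs). With multimapping reads in the total, by construction smaller, the first 10 genes held 31.5%, and list shares in percent were 15.4 (neuron-enriched), 5.39 (HOX-cluster), 0.224 (oligodendrocyte-lineage), 0.554 (choroid plexus and multiciliated), 8.1 (let-7 family), 1.89 (miR-17-92), 0.0444 (pluripotency), 6.64 (Dlk1-Dio3 imprinted cluster), 0.2996 (Sfmbt2 intronic cluster), 0.012 (erythroid), 0.0259 (leukocyte), 2.03 (vascular), 0.00236 (liver), 0.00846 (epithelial), 0.211 (sensory organ), 0.0716 (endocrine and pancreatic), 0.222 (mesenchymal and fibroblast), 1.45 (identical-copy microRNAs). Multimapping reads were added to the total only and to no list, and how many of them come from microRNAs is not known. Unstranded counts gave leukocyte 0.0711%, liver 0.00406% and identical-copy 2.48%. Without identical copies, oligodendrocyte-lineage came to 0.0417% and let-7 family to 13.8%. Of 90 named levels, unstranded counts moved 10 by more than 1 SD, and TMM and DESeq2 scaling moved 0. A total without Mir99a, where Mir99a itself was not compared, moved 67 levels and left 22 within 1 SD. These numbers follow largely from the totals and from how small an SD of 2 libraries can be. A total without Mir99a is smaller and raises every other level by construction, and the unstranded total is larger. Depth limits what could be seen below 0.589 and 0.673 CPM.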

Other observations

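The correlation of shared sequence with level was tested only after the counts of Mir9-2 and the Mir124a hairpins had been seen and after the list comparison fixed in advance had missed its threshold. Opposite-strand reads at the 11 entries ranged from 27.1 CPM at Gm25641, the position of Mir9-1, to 5858 CPM. At Gm25252, the position of Mir376a, opposite-strand reads came to 5858 ± 333 CPM (SD, n = 2), and at Gm25927, the position of Mirlet7e in the same chromosome 17 region as Mir99b, to 5640 ± 82.4 CPM. At Gm24321, the position of Mir409 in the Dlk1-Dio3 region, they came to 4706 ± 62.3 CPM, at Gm24083 (Mir191) to 3280 ± 81.0 CPM and at Gm25301 (Mir378a) to 3080 ± 186 CPM. Mir142, a leukocyte microRNA, lies opposite Mir142b, with 1532 and 1094 opposite-strand counts.

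The low counts of some microRNAs made from identical copies, such as Mir9-2, were weighed against reads that fit several loci being left out. Over all listed genes with a sequence, the 919 hairpins that share 20 bases with another hairpin had a median log2(CPM + 1) lower by a difference of -0.40 than the 975 that share none (permutation p = 1e-05, the smallest possible), and 8.92% against 31.1% were detected. The comparison of the identical-copy list gave a permutation p of 0.533 and a sign that depended on the comparison set, and among detected hairpins those that share 20 bases were higher by 0.28 (permutation p = 0.526), so whether lost reads lower the class as a whole cannot be told apart from other differences between these sets. As a hypothesis from a second test, hairpins with more shared sequence may lose more reads: across 56 identical-copy hairpins, the shared share of a hairpin correlated with its level at Spearman's rho -0.38 (permutation p = 0.00436) and Pearson's r -0.48 (permutation p = 5e-05). Without the 5 Mir9 and Mir124a hairpins that prompted it, rho was -0.30 over 51 hairpins (permutation p = 0.0306), where hairpins are not independent replicates. The correlation cannot tell lost reads from low expression of a microRNA in this tissue.

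Neighbouring hairpins deviated together between the libraries. Each pool had its own library, so pool and library preparation cannot be told apart. As a hypothesis, hairpins made from one transcript may share the deviation of that transcript: across 116 adjacent pairs within 10 kb, Pearson's r of the log2 ratios was 0.727 and Spearman's rho 0.421 (permutation p = 0.0001 for each, the smallest possible). The value of r rested in part on Mir206 and Mir133b, without which it was 0.423 over 115 pairs, with a rho of 0.406. It was 0.362 over 52 deeply counted pairs. A hairpin can enter more than 1 pair, and only 75 of the 116 pairs lay outside the Dlk1-Dio3 region. The pairs are therefore not independent, and the permutation p can overstate the evidence.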
